A study of Mus musculus with 4 samples.

How the data were processed

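Protein-DNA contacts in adult mouse liver were assayed by ChIP-exo, in which chromatin is immunoprecipitated and the DNA ends are trimmed by an exonuclease up to the crosslinked protein before sequencing. Per the labels, livers of wild-type C3H mice were perfused with formaldehyde, nuclei were isolated and chromatin was sonicated. There were 4 libraries in 2 groups, namely 2 libraries made with an antibody against FoxA2, a forkhead transcription factor of hepatocytes and other endoderm-derived cells, and 2 made with control IgG. The series' design text calls the libraries of each group biological replicates.

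One processed file was analysed here, a list of FoxA2 regions without a header line. Each line held a chromosome, a start, an end, a strand and a negative number, which is treated here as the authors' deposited score. The deposited scores were sorted from the most to the least negative. The unit of the score is not given in the sources used here. Its least negative value, -6.645, lay just past the base-2 logarithm of 0.01, which is -6.64386, so the score could be a base-2 logarithm of a p-value with a threshold of 0.01. Scores were therefore used only within the list. Differences of median scores are in the authors' unstated unit, and a ratio of them holds only on that scale. Per the submitters' processing notes, CASAVA and BWA 0.6.2 were among the tools and mm8 and mm10 among the genome builds, without a stated role. The file's name gives mm8, and all coordinates below are mm8, counted from 1. The region caller, the meaning of the strand, the use of the IgG libraries and whether the replicates were pooled are not given in the sources used here.

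The list held 1 value per region and no value per library. Sequencing depth is therefore unknown, no value could be given an SD over replicates, and FoxA2 was not compared with IgG region by region. The planned quasi-likelihood count test was not run for the same reason. The planned motif, annotation and gene-list comparisons needed an mm8 genome or annotation and were not run. A RefSeq gene table of the later assembly GRCm38.p6 was not used for positions, because coordinates of different builds cannot be mixed.

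All computations were done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A chromosome's span was taken from the start of its first region to the end of its last, since chromosome lengths of this build were not used here. Counts per chromosome were compared with the share of the summed spans by two-sided exact binomial tests with Benjamini-Hochberg adjustment over 20 chromosomes. That test treats regions as independent, so a 95% bootstrap interval over 1 Mb windows (10000 resamples) was added. Gaps between neighbouring starts were compared with 100 random placements on the same spans, for which the smallest possible p is 0.00990. A second set of placements kept each region within its own 1 Mb window. Chains were runs of regions with gaps of at most 10000 bp. Relative strands were tested by 10000 permutations of the strands over all regions, for which the smallest p is 0.0001. Median scores were compared by 10000 permutations of the scores, which treat regions as independent. Intervals of shares are exact binomial (95%) and treat regions or pairs as independent. All tests describe this list, because regions are not replicates.

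Regions were named by a rule set before the data were examined, as were the chromosome, clustering and strand-balance comparisons. It took the 10 regions with the most negative scores, the 10 windows of 1 Mb with the most regions, and the 10 chains with the most regions. The planned rule used windows and chains only for a list without a score, and they were added here because no gene could be named. The spacing of pairs, their relative strand and the scores by distance to a neighbour were chosen after the data were seen. Alternatives were merging regions within 100 bp, keeping the 17610 better-scored regions, leaving out X or unplaced sequences, counting chains once, and a chain limit of 12500 bp.

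The comparisons were tested on simulated data made from 35200 randomly placed regions. With no effect, 0 chromosomes were called. That list was 1 draw with regions placed independently, as the binomial test assumes. It does not show how often that test gives false calls in clustered regions. When X regions were removed with a probability of 0.5, X was called with a recovered ratio to expectation of 0.539. The list with X regions removed was then given partners 50 to 100 bp away for some of its regions. Its share of gaps under 1 kb was 17.9%, against 1.56% in a random placement of the same list. The list with no effect had 1.43%.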

Results

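FoxA2 contacts in adult mouse liver were mapped by ChIP-exo with 2 FoxA2 libraries and 2 IgG control libraries. The question addressed here was where FoxA2 occupied the genome and how its regions were arranged along the chromosomes. The list held 35221 regions, each 16 bp wide, and no position occurred more than once. Of these, 35200 lay on 20 placed chromosomes, a mean of 13.8 regions per Mb of span. No region was listed on Y or on the mitochondrial genome. There was 1 list for the 4 libraries, so the values below carry no replicate error, and the depth behind them is unknown.

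Scores ranged from -386.971 to -6.645, with a median of -12.6 and quartiles of -20.5 and -9.05. A more negative score ranked higher in the authors' list. Only 305 regions (0.866%) had a score under -100, while 11676 (33.2%) had a score above -10. The regions were divided evenly between the strands. The plus strand held 17530 and the minus strand 17691, a plus share of 49.8% (95% exact interval 49.2% to 50.3%, two-sided exact binomial p = 0.394).

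The most negative score, -386.971, belonged to a minus-strand region on chromosome 17 from 39456100 to 39456115. It had 7 other regions within 10 kb, the nearest 801 bp away. A pair of regions on chromosome 11 ranked second and sixth. The plus-strand member lay from 3061504 to 3061519 with a score of -385.677, and the minus-strand member, 18 bp away, from 3061486 to 3061501 with a score of -296.446. The region on chromosome 3 from 83106534 to 83106549 scored -348.535 and lay 121 bp from its nearest neighbour. The region on chromosome 1 from 163215499 to 163215514 scored -330.257, and the nearest region was 64 bp away. On chromosome 4, the region from 135487079 to 135487094 scored -318.08 and lay 16 bp from another. The remaining members of the 10 were on chromosome 3 from 81512854 (score -288.292), chromosome 8 from 129496049 (-286.971), chromosome 11 from 24469961 (-240.35) and chromosome 4 from 41819030 (-235.737). Each of the 10 had at least 2 other regions within 10 kb.

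FoxA2 regions were unevenly divided among chromosomes. The X chromosome had the fewest per Mb of span and chromosome 19 the most. X held 592 regions, or 3.73 per Mb (95% bootstrap interval 3.02 to 4.50), where 2191 were expected from its span. Its density was 0.258 times that of the autosomes (0.208 to 0.312), and the lowest autosomal density, on chromosome 14, was 11.8 per Mb. Chromosome 19 held 1366 regions, or 23.6 per Mb (19.5 to 27.8), which was 1.71 times its expectation (1.40 to 2.03). Chromosome 11 held 2098, or 17.7 per Mb (15.4 to 20.1), 1.28 times its expectation (1.11 to 1.46).

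By the exact binomial test, 15 of the 20 chromosomes departed from expectation at an adjusted p under 0.05, with 9 above it and 6 below. The adjusted p was 1.65e-74 for chromosome 19 and 8.61e-29 for chromosome 11, and that for X was too small to be represented. The number of regions per 1 Mb window varied far more than under random placement, with a variance of 13.3 times the mean against 1.78 times. With the bootstrap interval, which resamples windows and is not adjusted over chromosomes, 3 chromosomes remained apart from expectation: 19 and 11 above it and X below. With each chain counted once, the binomial test called 12.

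**Figure D1:**
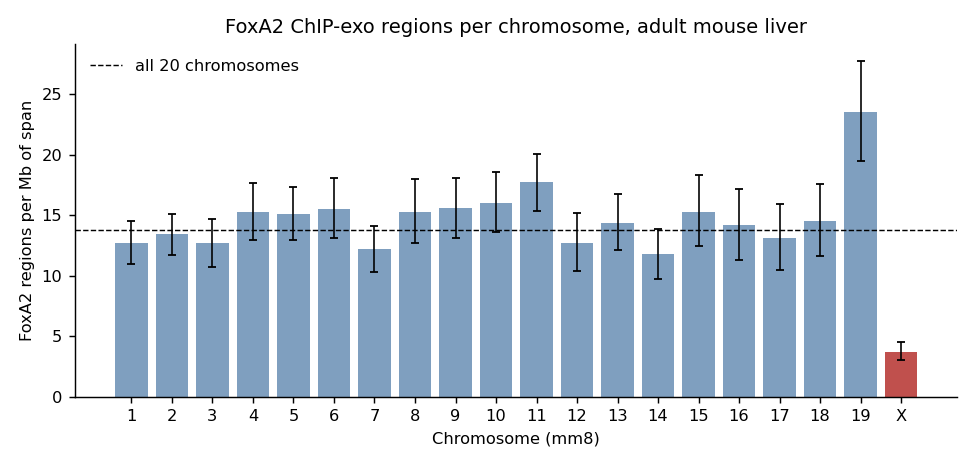
Bars give FoxA2 regions per Mb of span for each mm8 chromosome (X in red), error bars the 95% bootstrap interval over 1 Mb windows, and the dashed line the mean of 13.8 over all 20 chromosomes. X lies at 3.73 and chromosome 19 at 23.6 regions per Mb.

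The regions on X also had weaker scores. Their median was -11.1, against -12.6 on the autosomes, a difference of 1.53 (two-sided permutation test, p = 0.00070). Among the 8800 regions with the most negative scores, the X density was 0.180 times the autosomal density (0.133 to 0.235). Among the 8800 with the least negative scores it was 0.322 times (0.260 to 0.390). Of 158 full 1 Mb windows on X, 45 (28.5%) held no region, against 310 of 2367 autosomal windows (13.1%). The longest stretch without a region was also on X, from 22998166 to 32388877.

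FoxA2 regions were strongly clustered. The median gap between neighbours was 8890 bp, with quartiles of 547 and 46462 bp. Gaps under 1 kb made up 28.6% of all gaps, against a mean of 1.44% and a highest value of 1.57% in 100 random placements, a 19.8-fold excess. Gaps under 5 kb were 6.09-fold and gaps under 50 kb 1.48-fold more frequent than at random. Each excess had a permutation p of 0.00990, the smallest that 100 random placements allow. Placing regions at random within their own 1 Mb window keeps the large-scale density. Against this, the excess was 11.1-fold for gaps under 1 kb, 3.54-fold under 5 kb and 1.15-fold under 50 kb. With regions within 100 bp merged, gaps under 1 kb made up 18.7% of gaps. This was a 14.8-fold excess over random placement of the merged sites on the spans.

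Joining regions over gaps of at most 10 kb gave 17028 chains, of which 9288 were single regions. Chains with more than a single member held 73.6% of the regions, against a mean of 25.2% under random placement over the spans and 38.5% under placement within 1 Mb windows. There were 173 chains of 10 or more regions, holding 2083 regions. Random placement over the spans gave no such chain in any of 100 draws, and placement within 1 Mb windows gave at most 4.

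The largest chains held 23 regions each. The chain on chromosome 15 ran from 96832455 to 96878408, with 8 regions on the plus and 15 on the minus strand and a best score of -82.563. The chain on chromosome 18 ran from 84983150 to 85028988, with 16 plus and 7 minus regions and a best score of -139.919. Next came a chain of 22 regions on chromosome 3 from 98321850 to 98377681 and a chain of 20 on chromosome 10 from 87287508 to 87364564. Chromosome 8 held 3 of the 10 largest chains. These had 19 regions from 42356616 to 42402856, 18 from 42614119 to 42657037 and 18 from 112862224 to 112893707. The rest lay on chromosome 4 from 149694179 to 149719161 (18 regions), chromosome 1 from 67036713 to 67068273 (17) and chromosome 16 from 22792906 to 22815760 (17).

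**Figure D2:**
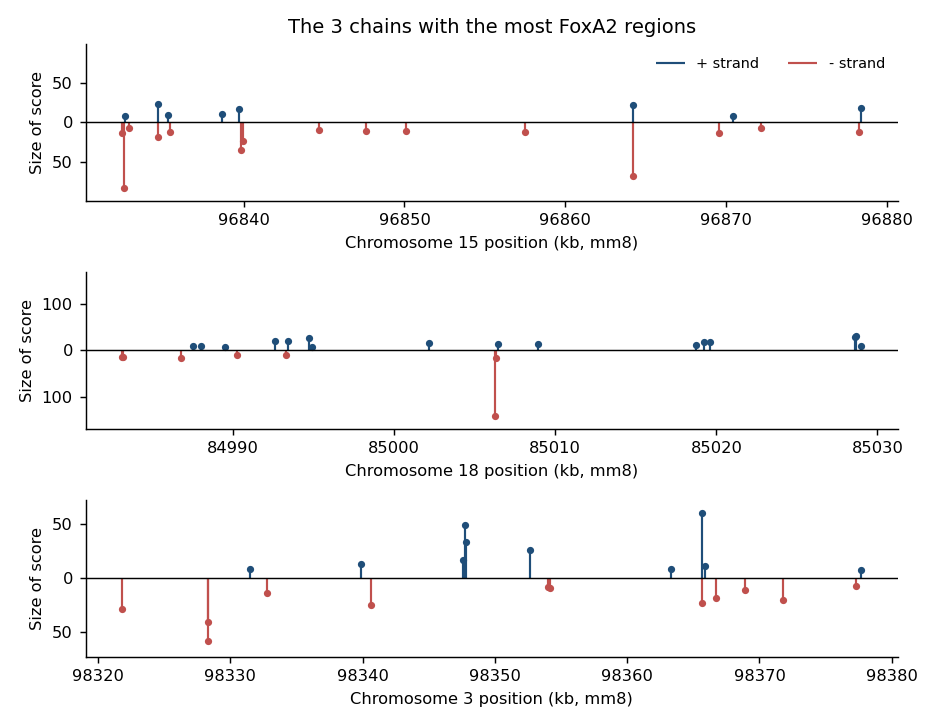
Each panel shows a chain, with position in kb (mm8) on the horizontal axis and the size of the authors' score on the vertical axis, plus-strand regions drawn upwards in blue and minus-strand regions downwards in red. The chains on chromosomes 15 and 18 hold 23 regions each and the chain on chromosome 3 holds 22, with median scores of -12.1, -14.3 and -17.9, respectively.

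At the scale of 1 Mb, a window held a median of 10 regions. The densest window, on chromosome 6 from 72000001 to 73000000, held 80 regions in 24 chains, and its best score was -91.207. The window on chromosome 8 from 129000001 to 130000000 held 75 regions, among them the region with the score of -286.971. Windows with 73 regions lay on chromosome 4 from 149000001 and on chromosome 8 from 42000001, the latter containing 2 of the 10 largest chains. Windows on chromosome 10 from 67000001 and from 127000001 held 71 and 69 regions. The window on chromosome 19 from 55000001 held 67, that on chromosome 15 from 82000001 held 66, that on chromosome 5 from 91000001 held 65 and that on chromosome 15 from 96000001 held 64. The highest count in any random placement over the spans was 41. Windows without any region made up 14.1% of the 2525 full windows, against a mean of 0.138% at random.

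At the shortest range, the distances between pairs of FoxA2 regions had a broad maximum. Among all 14180 pairs under 1000 bp apart, the fullest 10 bp class was 60 to 69 bp between starts, with 661 pairs against a mean of 9.26 in placements within 1 Mb windows, a 71.4-fold excess. The classes around it were nearly as full, with 555 pairs at 50 to 59 bp, 613 at 70 to 79 bp and 545 at 90 to 99 bp. No test set the class of 60 to 69 bp apart from these. Distances under 50 bp were less frequent, with 315 pairs at 20 to 29 bp and 59 under 10 bp. The number then declined with distance, from 3356 pairs at 100 to under 200 bp to 1633 at 200 to under 300 bp and 495 at 900 to under 1000 bp, where the excess was still 5.30-fold. Of the placed regions, 7905 (22.5%) had a neighbour within 100 bp and 11965 (34.0%) within 200 bp. Pairs under 16 bp apart, whose regions overlap, numbered 171.

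The relative strand of a pair depended on its distance. Of 288 pairs under 20 bp apart, 190 lay on the same strand (66.0%, 95% exact interval 60.2% to 71.4%). From 20 to under 200 bp the share was 52.6% (51.5% to 53.8%, 3925 of 7455 pairs), and from 200 to under 1000 bp it was 50.4% (49.1% to 51.6%, 3242 of 6437 pairs). By permutation of the strands, adjusted over the 3 ranges, p was 0.00015 for each of the shorter ranges, resting on the smallest p that the permutations allow, and 0.563 for the longest. When 100 classes of 10 bp were tested one by one, only that of 10 to 19 bp passed, at 65.9% (adjusted permutation p = 0.010).

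**Figure D3:**
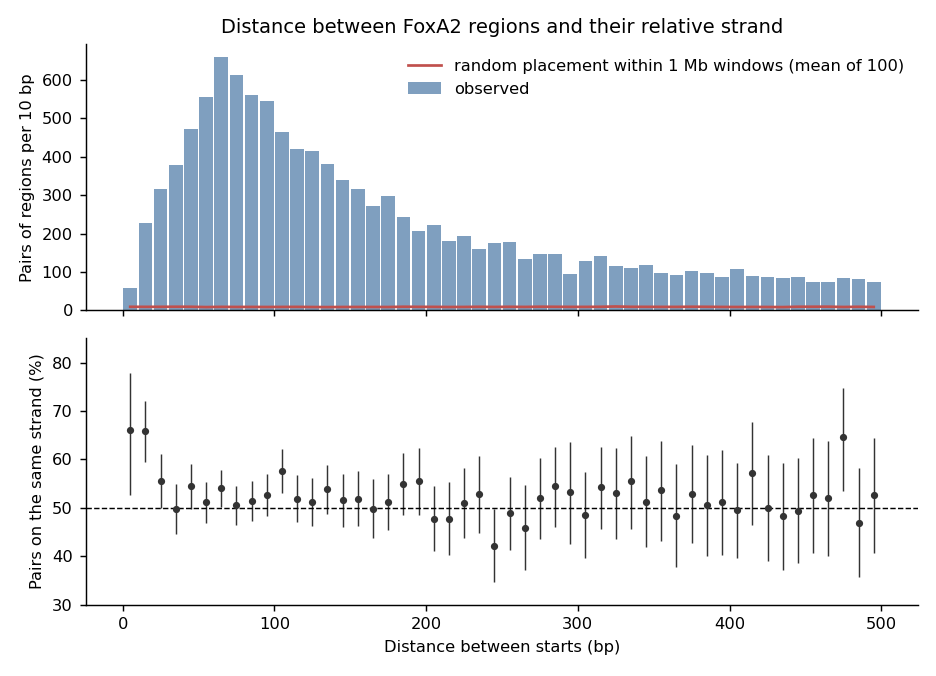
The upper panel plots the number of pairs of regions per 10 bp of distance between starts (bars) and the mean of 100 random placements within 1 Mb windows (line); the lower panel plots the percentage of pairs on the same strand with 95% exact intervals and a dashed line at an even split. Pairs are most frequent at 60 to 69 bp, and the same-strand share is 66.0% under 20 bp.

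Regions with a close neighbour had more negative scores. The median was -19.5 (95% bootstrap interval -20.1 to -18.9) in 2883 regions with another within 50 bp, and -16.3 (-16.8 to -15.9) in 5022 regions whose nearest lay 50 to 100 bp away. It was -13.2 (-13.7 to -13.1) at 100 to 200 bp and -12.0 (-12.1 to -11.6) at 200 to 500 bp. Regions with none within 50 kb had a median of -10.6 (-11.1 to -10.6). The 7905 regions with a neighbour within 100 bp differed from these 2999 isolated regions by -6.73 in median score (two-sided permutation test, p = 0.0001, the smallest possible). That test counts both members of a close pair as separate regions, although the scores of such pairs were related.

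**Figure D4:**
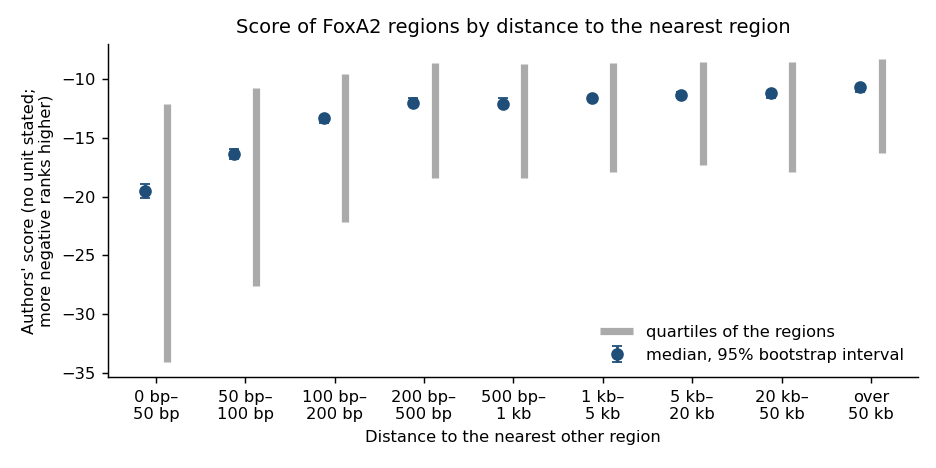
Points give the median authors' score of FoxA2 regions by distance to the nearest other region, with 95% bootstrap intervals, and grey bars the quartiles of the regions. The median moves from -19.5 within 50 bp to -10.6 beyond 50 kb.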

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

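Of 21 regions on unplaced sequences, which the comparisons between chromosomes do not use, some lay on sequences with more than 3 regions, the limit set for a closer look. The counts were not set against the lengths of these sequences. The unplaced sequence of chromosome 13 held 4 regions with a best score of -43.941. The sequences assigned to no chromosome held 12 regions with a best score of -53.209. The unplaced sequences of chromosomes 1 and 7, with 2 and 3 regions, did not exceed this. No explanation was tested for these.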

How the results depend on the processing

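Of 40 alternative values, 2 moved. The other 38 kept their direction and side of the threshold where a test was run; untested counts and shares stayed within 1.5 times the reported value, and the fullest class of pair distances kept its place. Some of the 38 could not move or could hardly move. No position occurred more than once, unplaced sequences held 21 regions, and the adjacent pairs under 20 bp apart were the same 288 pairs. Every clustering setting had the smallest p that the placements allow. Keeping the better-scored regions left 17610 regions by construction. The bootstrap interval over 1 Mb windows set 3 chromosomes apart in place of the 15 of the binomial test. It is not adjusted over chromosomes, but leaving out an adjustment can only add calls and cannot account for the fall. The bootstrap carries the spread between windows, whose variance was 13.3 times the mean, and the binomial test does not. Under the other 4 settings of the chromosome test the count ran from 12 to 16. The ratio of X to its expectation ran from 0.218 in the better-scored regions to 0.397 with chains counted once, and that of chromosome 19 from 1.58 to 1.73. The excess of gaps under 1 kb ran from 11.1-fold to 32.3-fold. The fullest class of pair distances began at 60 bp in all 4 alternatives, and the same-strand share under 20 bp stayed between 66.0% and 68.8%. The bootstrap setting, chains counted once and the alternatives for pairs and scores were chosen after seeing the data. No paired analysis was possible because the list carries no value per library, and for the same reason no replicate could be left out and no test with another count tool was run. The alternatives set for motifs, annotation and gene lists were not run. Depth is unknown, so it cannot be said which missing regions were too shallow to call.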

Other observations

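Over all overlapping FoxA2 regions, 110 pairs lay on the same and 61 on opposite strands. Taken one by one, 1 of 13 distances passed the test, which treats pairs as independent. Distances with few pairs could not have passed, and the same-strand excess was not confined to 4 bp. At 4 bp, 13 pairs lay on the same strand and 0 on opposite strands (exact binomial, adjusted over 13 distances, p = 0.00317). At 8 bp, 8 pairs lay on each arrangement, and at 13 bp 20 pairs lay on the same and 8 on opposite strands (adjusted exact p = 0.232). Large stretches lacked regions elsewhere than on X too, on chromosome 14 from 79214318 to 85252790 and on chromosome 1 from 145960039 to 151939730.

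Of the tests below, those of halved X reads, of region-rich surroundings (by medians and by ranks), of overlapping regions, of a caller's minimum distance, of a nucleosomal spacing and of steps of 4 bases were chosen after the result they bear on had been seen.

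For the low density of regions on X, empty or unreadable stretches that leave whole 1 Mb windows without regions are argued against as the whole cause. Among 1 Mb windows with at least 1 region, the X median was 4 regions against 14 on autosomes, a ratio of 0.286 (95% bootstrap interval 0.214 to 0.308). Shorter unreadable stretches spread over X were not tested. A loss of weak regions only is argued against by the ratio of 0.180 (0.133 to 0.235) in the best-scored 8800 regions. A single X copy, as in male mice, could halve the reads there. If scores scaled with reads, 46.1% of autosomal regions would still pass, and the X density was 0.558 times that value. Neither the sex of the mice nor the link between reads and score is in the labels. Halved reads, shorter unreadable stretches and lower FoxA2 occupancy of X therefore cannot be told apart.

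The second pattern is the stronger score of regions with a close neighbour. Regions with the nearest neighbour at 1 to 5 kb showed 0.146 times the shift in median score (0.0783 to 0.157) of those within 100 bp. By ranks, which need no unit, the excess over an even chance of outranking an isolated region was 0.193 times theirs (0.137 to 0.250). A neighbour at 1 to 5 kb with none closer therefore went with only a small part of the shift. The number of regions around each was not matched between these groups. The test thus cannot separate region-rich surroundings from close neighbours. In isolated pairs, the scores of the members were related under 100 bp (Spearman rho of 0.267 across pairs, which are not replicates) and had a rho of -0.00878 (-0.0802 to 0.0578) from 200 to 500 bp, a difference of 0.276 (0.199 to 0.352), as reads shared between neighbours would give. If shared reads acted most in overlapping regions, rho should be at least as high there. It was 0.0932 (-0.132 to 0.325) in 69 such pairs against 0.408 (0.334 to 0.476) at 16 to 49 bp, a difference of -0.315 (-0.558 to -0.0771). This argues against shared reads for overlapping regions only under that assumption, since how the caller divides reads between them is not known. For regions from 16 to 99 bp apart, shared reads, extra calls beside strong sites, joint occupancy of a short element and region-rich surroundings all remain open.

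The third pattern is the broad maximum in pair distances, fullest at 60 to 80 bp. A minimum distance set by the region caller is argued against by 1453 pairs under 50 bp apart, though a caller that resolves close sites less often remains open. Copies of a repeated sequence in a few places are argued against, since the 2934 pairs 50 to 99 bp apart occurred in 2335 chains. The 100 largest chains held 6.10% of these pairs. Those chains hold few of the regions, so their share could hardly have been large and decides little. Copies spread over many places remain open, because no annotation of repeats was used. A second mode at the spacing of neighbouring nucleosomes was not seen, with 972 pairs at 170 to under 210 bp, 1.01 times the interpolated value (95% Poisson interval 0.945 to 1.07). A period of 10 to 11 bp, as turns of the DNA helix might give, stayed undecided, with a power at percentile 58 of 1000 curves drawn from the smoothed counts.

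One hypothesis concerned the same-strand excess of overlapping regions, although the excess was not particular to them. The 117 pairs under 20 bp apart that did not overlap had a same-strand share of 68.4% (strand permutation, p = 0.00020). A forkhead site can overlap a copy of itself shifted by 4 bases, which could place several same-strand regions at 4, 8 or 12 bp. These distances held 26.4% of 110 same-strand and 23.0% of 61 opposite-strand pairs, a difference of 3.41 percentage points (Fisher's exact test, two-sided, p = 0.714). The test therefore did not decide, and the excess at 4 bp was noticed in the same data.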
